A study of Homo sapiens with 5 samples.

How the data were processed

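Expression was measured in the Hodgkin lymphoma cell line KM-H2 after 16 hours with 30 uM LY294002 or with its solvent DMSO, on Affymetrix arrays hybridised with biotin-labelled cRNA made from total RNA, per the labels' protocols. The series design describes triplicates in both groups and 1 array left out for high background, so 3 DMSO arrays and 2 LY294002 arrays were available. The deposited table holds probe set values on a log2 scale, and the authors made them with the R package affy, per the submitters' processing notes. The version, the background correction and the summary method are not given in the sources used here. The quartiles of the 5 columns were close but not equal. The values were taken as already normalized between arrays and were used as deposited. The upper quartile was 7.69 on LY294002 replicate 1 and 7.60 to 7.62 on the other arrays. That gap is of the order of the median size of a gene's log2 change, 0.0764. For arrays, their number limits the precision, and there is no depth of sequencing to report.

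The table holds 8793 probe sets without missing values. The 47 control probe sets were left out, and 8746 were fitted. Gene names came from the platform's annotation table: 7840 probe sets had 1 gene symbol, 388 had several and 518 had none there. The gene identifiers of 7838 of the 7840 were found in the RefSeq gene table, and 0 symbols needed an update. Probe sets with several symbols or none stayed in the fit and named no gene. A gene with more than 1 probe set (122 genes) was represented by its brightest, which gave 7713 genes; 1 of the 122 had a probe set past the threshold, and in 0 did probe sets past it differ in sign. Probe sets whose name marks them as shared by several transcripts, which includes those of many histone and HLA genes, can bind RNA of near-identical genes. No genome coordinates are given, because no build is named for the array.

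LY294002 was compared with DMSO by limma (lmFit and eBayes, version 3.58.1, in R 4.3.3, with statmod 1.5.0), with the group as the only term and Benjamini-Hochberg adjustment over the 8746 probe sets at a threshold of 0.05. The fit has 3 residual degrees of freedom. Errors given with log2 fold changes are the standard errors of this fit, from 3 DMSO and 2 LY294002 arrays, and folds are 2 to the power of the log2 difference. A total of 31 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera was repeated with the correlation estimated from the data, which in limma also bases the test on the 3 residual degrees of freedom alone. Fry, a test of whether the genes of a list move on balance in 1 direction, was an alternative. For each list, members past the threshold were counted over all genes and adjusted over the list alone.

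The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes are the 8 highest and the 8 lowest log2 fold changes among genes past the threshold whose LY294002 arrays lay outside the DMSO range and whose higher group mean reached the median of all probe sets, up to 3 members past the threshold for each list that passed and up to 1 for each other list, and a set of genes fixed by name, of which PIK3IP1 has no probe set here. Genes outside the rule are said to be chosen after their values were seen. XIST and Y-linked genes are not named. The alternatives were quantile normalization, median centring, the dimmest 40% of probe sets left out, an intensity trend with a robust prior, array weights, the replicate number as a block, no variance moderation, the mean of a gene's probe sets, a fold threshold of 2, and each array left out in turn. Cyclic loess and the removal of probe sets with identical values on arrays of the same group were added after seeing the data.

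The tests were tested on simulated data: on 10 simulated tables with the moderated spread of these 8746 probe sets, limma called 85.4% of log2 changes of 0.5, 98.5% of changes of 1 and 100% of changes of 2, and 4.54% of its calls were unchanged probe sets. Camera, on 7713 simulated genes, called 100% of lists shifted by 0.3 and 1% of unchanged lists. These simulations hold no correlation between genes and no identical values. They also take the moderated spread as the true one, so the shares called need not hold for these data. In the data, 24 genes with separated groups were at least 2-fold higher and 8 at least 2-fold lower. Of all genes, 14 and 6 changes of that size passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.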

Results

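Gene expression was profiled on 5 arrays of KM-H2, an established line of B-lineage Hodgkin lymphoma cells. The cells had been kept for 16 hours with 30 uM LY294002 (2 arrays) or with DMSO (3 arrays). LY294002 is a morpholine compound used as an inhibitor of phosphoinositide 3-kinase (PI3K), and it is also known to bind mTOR and the bromodomains of BET proteins. Array medians lay between 6.26 and 6.29 on the log2 scale, while the upper quartile was 7.69 on LY294002 replicate 1 and 7.60 to 7.62 on the other arrays. Across probe sets, Pearson's r was 0.996 to 0.998 between arrays of the same group and 0.989 to 0.992 between groups. The 3' minus 5' difference of the ACTB control probe sets, a sign of RNA quality, was -0.82 ± 0.13 (SD, n = 3) with DMSO and -0.79 ± 0.10 (SD, n = 2) with LY294002. That of GAPDH was -0.17 ± 0.08 (SD, n = 3) and -0.14 ± 0.07 (SD, n = 2). Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

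The comparison of LY294002 with DMSO asks which genes respond to the inhibitor in Hodgkin lymphoma cells. Histone genes led the genes that rose: the linker histone gene H1-2 rose 4.87-fold (log2 2.28 ± 0.19), the core histone genes H2BC5 4.22-fold (2.08 ± 0.07), H2AC6 4.15-fold (2.05 ± 0.05) and H2BC12L 3.59-fold (1.85 ± 0.12), and the linker histone gene H1-10 3.43-fold (1.78 ± 0.13). HEXIM1, an inhibitor of the elongation factor P-TEFb, rose 2.81-fold (1.49 ± 0.12), RYBP, a partner of Polycomb proteins, 2.8-fold (1.49 ± 0.13), and DHRS2, a short-chain dehydrogenase, 2.76-fold (1.46 ± 0.07). Among genes that fell, the transcription factor gene TFEC changed by log2 -1.85 ± 0.17, the serotonin transporter gene SLC6A4 by -1.71 ± 0.07, and BLNK, an adaptor of the B cell receptor, by -1.48 ± 0.15. PCP4, a calmodulin-binding protein, changed by -1.16 ± 0.06, the galectin gene LGALS2 by -1.09 ± 0.08, the interferon-induced IFI27 by -1.02 ± 0.07, SPIB, an Ets factor of B cells, by -0.98 ± 0.05, and NME4, a nucleoside diphosphate kinase of mitochondria, by -0.85 ± 0.08. By the naming rule, both LY294002 arrays lie outside the range of the DMSO arrays in each of these 16 genes. Their limma adjusted p-values ran from 0.00399 to 0.0419.

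**Figure D1:**
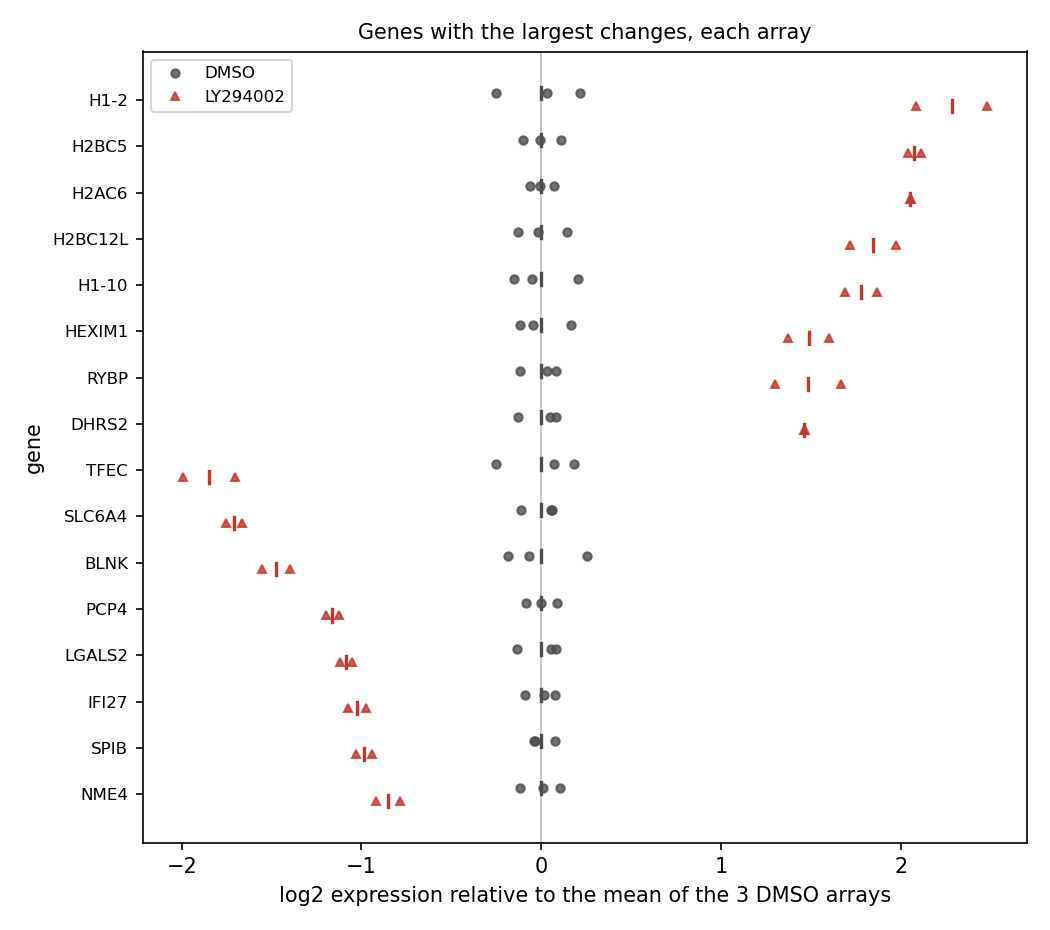
Expression of the 16 named genes with the largest changes on each array, as log2 values relative to the mean of the 3 DMSO arrays (horizontal axis), with circles for DMSO, triangles for LY294002 and vertical ticks for group means. H1-2 sits highest at 2.28 and TFEC lowest at -1.85. Genes were chosen by a rule that includes LY294002 arrays outside the DMSO range.

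In all, 70 of 7713 genes changed (47 higher and 23 lower with LY294002), of which 14 rose and 6 fell at least 2-fold. Over probe sets the count was 84 (57 higher and 27 lower); 8 of these carried several gene symbols and 6 none. Both LY294002 arrays lay above all DMSO arrays for 1246 genes and below them for 1037, together 29.6% of genes. Chance gives 20% where no values are tied, and many are tied here. The share was not computed for other splits of the arrays, so its spread is not known. Unadjusted p-values under 0.05 were found for 1320 genes. The number of genes past the limma threshold fell when 1 DMSO array was left out. It was 4 without DMSO replicate 1, and 0 without DMSO replicate 2 or DMSO replicate 3. These fits still had 946 to 1165 genes at an unadjusted p under 0.05. All 70 genes kept their sign without any 1 array. That says little, because they were chosen for differing on these same arrays. The count was 510 of 4771 genes without probe sets that hold identical values on arrays of the same group, a setting chosen after seeing the data. That removal takes out probe sets with a low spread within a group. The count was 299 after quantile normalization, 264 after cyclic loess (also chosen after seeing the data) and 203 without dim probe sets. It was 147 after median centring, 17 with array weights and 1 without variance moderation.

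Of 31 gene lists, 15 passed camera at the preset correlation, 7 higher and 8 lower with LY294002; 0 passed with an estimated correlation, where the smallest adjusted p was 0.235. With fry 7 passed: 5 of the 15 (BET inhibitor-induced genes, B cell identity, glycolysis, MHC class II, autophagy and lysosome) and, beyond them, FOXO-induced genes and the BCL2 family. The other 10 had adjusted p-values of 0.0567 to 0.352 with fry. Among the 15 lists, the correlation estimated from 3 residual degrees of freedom ran from -0.0699 (BET inhibitor-induced genes) to 0.419 (ATF4 and amino acid response). Where it lies far above the preset of 0.01, camera's p-values at the preset can be too small. The list with the largest shift held genes known to be induced by BET inhibitors, with a mean log2 fold change of 1.48 over 7 measured genes. Of these, 5 rose, namely H1-2, H2BC5, H2AC6, HEXIM1 and H2BC21, the last by 1.12 ± 0.08 on the log2 scale. H2BC12 was 1.32 ± 0.18 higher (limma adjusted p = 0.0645), and SERPINI1, a protease inhibitor, did not pass; H2BC21, H2BC12 and SERPINI1 lie outside the naming rule and were chosen after their values were seen. Adjusted over the list alone, 6 rose and 0 fell. Camera gave an adjusted p of 1.24e-08, and an adjusted p of 0.235 with an estimated correlation. The probe sets of H2BC5, H2AC6, H2BC12L and H2BC21 are of the kind that can bind near-identical histone transcripts, so their values are uncertain as values of single genes.

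Genes of the cell cycle differed by phase. The 25 genes measured for G2 and mitosis were higher by a mean of 0.27, with 25 of 25 log2 fold changes above 0. CDC20, the activator of the anaphase-promoting complex, rose by 0.79 ± 0.07, and the other 24 did not pass; adjusted over the list alone 7 rose and 0 fell. The 29 genes of S phase and DNA replication had a mean of -0.28, with 29 of 29 below 0. POLE2, a subunit of DNA polymerase epsilon, fell by 0.36 ± 0.04 (limma adjusted p = 0.053 with an intensity trend and robust prior), and adjusted over the list alone 10 fell and 0 rose. Camera's adjusted p was 1.99e-08 for each list, and each had an adjusted p of 0.418 with an estimated correlation. That correlation was 0.395 for G2 and mitosis and 0.329 for S phase and DNA replication, far above the preset of 0.01. The difference between the mitotic and the replication list was 0.02, -0.01 and -0.01 on DMSO replicates 1, 2 and 3, relative to their mean, and 0.53 and 0.58 on the LY294002 arrays.

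B cell genes had a mean of -0.27 and a median of -0.08 over 18 genes, so that a few genes carry the mean. The median member was at 6.18 on the DMSO arrays, below the array medians, and dim members can show little fall. BLNK, SPIB and CR2, the complement receptor of B cells, fell, the last by 0.76 ± 0.08, and the other 15 did not pass. MS4A1, the gene of the surface marker CD20, chosen after its values were seen, was at -0.999 ± 0.15 (limma adjusted p = 0.073). Adjusted over the list alone 6 fell and 1, BCL6, rose; camera's adjusted p was 0.0011, and the adjusted p was 0.418 with an estimated correlation. The 11 genes of MHC class II antigen presentation had a mean of -0.26, with HLA-DRB1 past the threshold at -0.49 ± 0.05 on a probe set that can bind other HLA-DRB transcripts. Adjusted over the list alone 6 fell and 0 rose; camera's adjusted p was 7.06e-05, and the adjusted p was 0.418 with an estimated correlation. For MHC class I the mean over 10 genes was -0.05 (-0.08 to -0.03 without 1 array) and the median 0.03, 0 genes passed, 2 fell when adjusted over the list alone, and camera's adjusted p was 0.802.

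IRF4, a factor of plasma cell differentiation that is also expressed in Hodgkin cells, rose by 0.66 ± 0.07. It was the 1 of 13 plasma cell genes to pass, over all genes and adjusted over the list alone, and the mean of that list was -0.03 (camera adjusted p = 0.783). PRDM1, which directs plasma cell differentiation, was 0.23 ± 0.07 higher (limma adjusted p = 0.217), and BCL6, its antagonist in germinal centre B cells, 0.37 ± 0.06 higher (0.0886). IRF4 was also the 1 of 20 Hodgkin and Reed-Sternberg cell-associated genes to pass. Adjusted over the list alone 4 rose and 3 fell, with a mean of -0.02, a median of 0.00071 and a camera adjusted p of 0.999. TNFRSF8, the gene of the diagnostic marker CD30, was at -0.68 ± 0.17 (limma adjusted p = 0.157).

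Of the genes tied to PI3K signalling, FOXO-induced genes had a mean of 0.17 and a median of 0.04 over 26 genes and did not pass camera (adjusted p = 0.181; 0.0454 with fry). MAP1LC3B, a protein of the autophagosome membrane, was the 1 gene to rise, by 0.64 ± 0.06; adjusted over the list alone 6 rose and 2 fell. CDKN1B, the cell cycle inhibitor p27, was 1.21 ± 0.30 higher (limma adjusted p = 0.157), FOXO3 0.77 ± 0.18 (0.139) and FOXO1 0.08 ± 0.05 (0.438), while IRS2, an adaptor of the insulin receptor, stood at 0.0029 ± 0.10 (0.993). The 17 components of the PI3K, AKT and mTOR pathway had a mean of 0.12, with 0 genes past the threshold and, adjusted over the list alone, 5 rising and 2 falling. The adjusted p from camera was 0.0455, and the adjusted p was 0.418 with an estimated correlation. That call was lost without DMSO replicate 1 (mean 0.11, adjusted p = 0.0553), DMSO replicate 3 (0.11, 0.0644) or LY294002 replicate 1 (0.07, 0.497), and also after quantile normalization (0.09, 0.0618), after cyclic loess (0.11, 0.0687), without dim probe sets (0.18, 0.079) and with fry (0.102). Autophagy and lysosome genes were higher by a mean of 0.21 over 17 genes: SQSTM1, an autophagy receptor, rose by 0.70 ± 0.06 beside MAP1LC3B, and adjusted over the list alone 3 rose and 0 fell. Camera's adjusted p was 0.000255, and the adjusted p was 0.418 with an estimated correlation.

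Genes of glycolysis were lower, with a mean of -0.28 over 20 genes. Lactate dehydrogenase LDHA changed by -0.69 ± 0.03, phosphoglycerate mutase PGAM1 by -0.59 ± 0.05 and phosphoglycerate kinase PGK1 by -0.44 ± 0.05, the other 17 did not pass, and adjusted over the list alone 11 fell and 0 rose. The adjusted p from camera was 6.25e-06, and the adjusted p was 0.418 with an estimated correlation. For MYC and its other targets the mean was -0.22 over 17 genes, with 0 past the threshold and, adjusted over the list alone, 6 lower and 0 higher. Camera's adjusted p was 0.000664, the adjusted p was 0.436 with an estimated correlation, and without LY294002 replicate 2 the mean was -0.15 and the call was lost (adjusted p = 0.277). MYC itself was at 0.0018 ± 0.09 (limma adjusted p = 0.999), and CCND2, a D-type cyclin, at -0.14 ± 0.08 (0.438), or -0.02 without LY294002 replicate 2 and -0.26 without LY294002 replicate 1. The 42 cytosolic ribosomal protein genes were higher by a mean of 0.15, 39 of them with a log2 fold change above 0 and 0 past the threshold, over all genes and adjusted over the list alone. The adjusted p from camera was 2.53e-08, and the adjusted p was 0.418 with an estimated correlation.

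ATF4 and amino acid response genes had a mean of -0.18 over 29 genes, with 0 past the threshold either over all genes or adjusted over the list alone, a camera adjusted p of 0.0155, and an adjusted p of 0.613 with an estimated correlation. On this list DMSO replicate 1 stood apart, at 0.22 against -0.09 and -0.13 on the other DMSO arrays. Without DMSO replicate 1 the mean was -0.08 (adjusted p = 0.0943) and without LY294002 replicate 2 it was -0.14 (adjusted p = 0.504), so that the call was lost in either case. Fatty acid synthesis genes had a mean of -0.18 over 8 genes and did not pass camera (adjusted p = 0.133). Among settings that keep both LY294002 arrays, they passed camera without dim probe sets (-0.25, 0.0378) and without DMSO replicate 3 (-0.23, 0.0367). They also passed with the replicate block (-0.23, 0.0212). The block has the mean of the fit without DMSO replicate 3, because no LY294002 array shares that number and the block absorbs it. For the fits of this list with 1 LY294002 array only the mean is given. It was -0.25 without LY294002 replicate 1 and -0.10 without LY294002 replicate 2. Among the fatty acid genes ACACA, acetyl-CoA carboxylase, fell by 0.34 ± 0.03 (limma adjusted p = 0.0555 with an intensity trend and robust prior). It was also the 1 gene to fall when adjusted over the list alone. For cholesterol synthesis and uptake the mean was -0.12 over 17 genes (camera adjusted p = 0.19), for ribosome biogenesis -0.08 over 11 (0.181), for oxidative phosphorylation -0.03 over 25 (0.615), for ER chaperones and the unfolded protein response -0.03 over 12 (median -0.0055, 0.866), and for heat shock genes 0.10 over 8 (median 0.03, 0.381). In these 5 lists 0 genes passed, over all genes or adjusted over the list alone. The cholesterol list passed camera without DMSO replicate 2 (-0.16, 0.0331) or DMSO replicate 3 (-0.15, 0.0469). It also passed with the replicate block (-0.15, 0.0347), which has the mean of the fit without DMSO replicate 3. DMSO replicate 1 stood apart on this list, at 0.16 against -0.09 and -0.07. Without DMSO replicate 1 the mean was -0.03 (camera adjusted p = 0.632), and without LY294002 replicate 2 it was -0.08. Ribosome biogenesis passed after quantile normalization (-0.13, 0.0107), after cyclic loess (-0.10, 0.0266) and without LY294002 replicate 1 (-0.12, 0.0162), while without LY294002 replicate 2 its mean was -0.05 (0.942) and its median over all arrays was -0.04. Hypoxia-induced genes had a mean of -0.15 over 14 genes (camera adjusted p = 0.228; -0.10 without DMSO replicate 1, which stood apart at 0.10 against -0.05 and -0.05), with 0 past the threshold and 2 lower when adjusted over the list alone. NRF2 targets had a mean of 0.03 and a median of -0.04 over 10 genes (camera adjusted p = 0.574; mean 0.0094 without DMSO replicate 3), with 0 past the threshold and 1 higher when adjusted over the list alone.

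NF-kB targets were higher by a mean of 0.28 over 24 genes, with 0 past the threshold and, adjusted over the list alone, 11 higher and 0 lower. Camera's adjusted p was 0.000175, and the adjusted p was 0.418 with an estimated correlation. The chemokine receptor gene CCR7, which is also on the list of FOXO-induced genes and was chosen after its values were seen, was 1.14 ± 0.18 higher (limma adjusted p = 0.0776). ERK feedback and immediate early genes had a mean of 0.36 over 15 genes, with 0 past the threshold and, adjusted over the list alone, 8 higher and 1 lower. The adjusted p from camera was 0.00133, and the adjusted p was 0.436 with an estimated correlation. ETV5, an Ets factor induced by ERK, also chosen after its values were seen, was 1.27 ± 0.17 higher (limma adjusted p = 0.059). IER3 is on both the NF-kB and the ERK list, so their means are not fully separate. DMSO replicate 1 was the lowest array on both lists, at -0.09 for NF-kB targets and -0.13 for ERK feedback genes. Interferon-stimulated genes had a mean of -0.22 over 22 genes; IFI27 fell, and adjusted over the list alone 6 fell and 1 rose. Camera's adjusted p was 0.00337, the adjusted p was 0.418 with an estimated correlation, and the call was lost without LY294002 replicate 2 (mean -0.23, adjusted p = 0.0984). In the BCL2 family PMAIP1, the BH3-only protein NOXA, rose by 0.41 ± 0.05 (limma adjusted p = 0.0534 with an intensity trend and robust prior). The mean of the family over 14 genes was 0.10 and the median 0.04 (camera adjusted p = 0.21; 0.0454 with fry), and adjusted over the list alone 3 rose and 0 fell. The p53 targets had a mean of -0.09 and a median of -0.0029 over 15 genes (camera adjusted p = 0.209). Their mean was -0.16 and passed without LY294002 replicate 1 (0.00904), and was -0.02 without LY294002 replicate 2 (0.942). Over all arrays 0 of them passed the threshold and, adjusted over the list alone, 4 fell and 0 rose.

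Markers of other cell types were included because a culture can hold more than 1 kind of cell. T and NK cell markers had a mean of -0.11, with 12 of 12 genes below 0 and 0 past the threshold, over all genes or adjusted over the list alone. The adjusted p from camera was 0.0134, the adjusted p was 0.418 with an estimated correlation, and the call was lost without LY294002 replicate 1 (mean -0.07, adjusted p = 0.159). The brightest of these markers was CD4, at 8.99 on the DMSO arrays, and the median marker was at 6.72. Myeloid markers had a mean of -0.09 and a median of -0.03 over 8 genes (camera adjusted p = 0.19), and stromal, endothelial and epithelial markers -0.08 over 12 genes (0.19), with 0 genes past the threshold in both lists, over all genes or adjusted over the list alone.

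**Figure D2:**
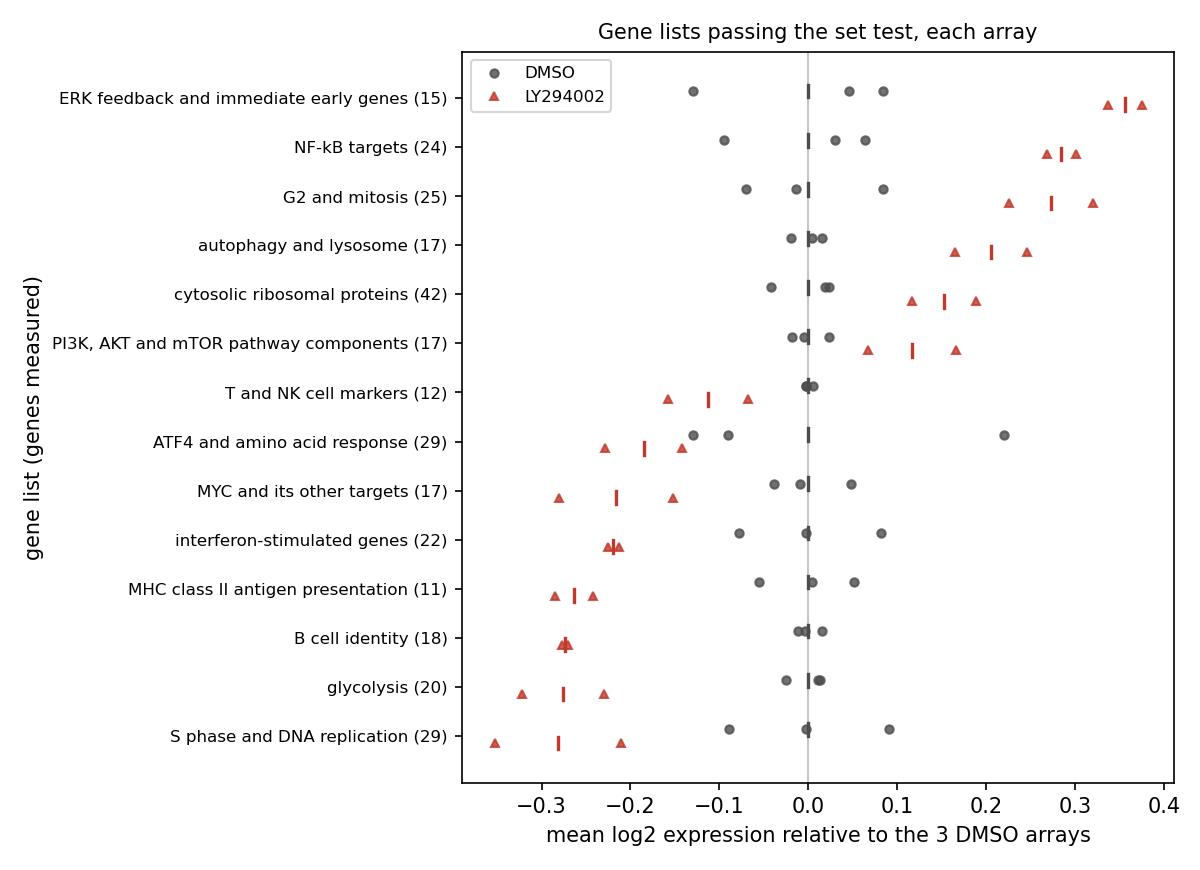
Mean log2 expression of 14 gene lists that passed camera at the preset correlation, on each array relative to the mean of the 3 DMSO arrays (horizontal axis), with circles for DMSO, triangles for LY294002, vertical ticks for group means and the number of genes measured in parentheses; the list of BET inhibitor-induced genes, at 1.48, is left out to keep the scale. The lists range from a mean of 0.36 for ERK feedback genes to -0.28 for S phase and DNA replication, and DMSO replicate 1 lies apart at 0.22 for the ATF4 list.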

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

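Of the 70 changed genes, all that were tested kept their sign under every alternative. They were chosen on these same arrays, so the kept signs are not separate evidence. The count depended on the setting. Against 70 genes (47 higher and 23 lower) it was 299 (172 and 127) after quantile normalization, 147 (99 and 48) after median centring, 203 (141 and 62) without dim probe sets, 101 (75 higher) with an intensity trend and robust prior, 17 (12 and 5) with array weights, 1 (1 and 0, HES1 at 0.11, not among the 70) without variance moderation, 20 (14 and 6) with a fold threshold of 2, and 87 with the mean of a gene's probe sets. Of settings chosen after seeing the data, cyclic loess gave 264 (168 and 96) and the removal of tied probe sets 510 (349 and 161); the 70 genes remained past the threshold after quantile normalization, median centring and cyclic loess, and 69 of 69 tested did without tied probe sets. The intensity trend with robust prior kept 63 of the 70; TUFM, ZFAND6, PMAIP1, POLE2, ACACA, PGLS and GSTM1 ended at adjusted p-values of 0.051 to 0.0555. Leaving out 1 array gave 0 to 4 genes (0 to 4 higher and 0 to 0 lower), in fits that lose 1 of 3 residual degrees of freedom and assume that a lone LY294002 array varies as the DMSO arrays do; the 4 genes, without DMSO replicate 1, were DHRS2, H2BC5, H2AC6 and H2BC12. The replicate numbers showed no sign of pairing. Deviations of same-numbered arrays correlated at 0.002 and -0.213, and the differences between numbers 1 and 2 at -0.105. All of these rest on 1 contrast between the 2 LY294002 arrays, so a shared culture or day cannot be excluded. With the replicate number as a block, which leaves 1 residual degree of freedom, limma called 0 genes (0 higher and 0 lower), with 820 at an unadjusted p under 0.05. Camera then passed 17 gene lists, with the cholesterol and fatty acid lists gained. The block absorbs DMSO replicate 3, the only array with its number, so its estimates are those of the fit without that array. Against 15 lists, camera passed 0 with an estimated correlation, fry 7, each scaling 15, 15 of 30 without dim probe sets, and fits without 1 array 12 to 16. Equal counts hide exchanges: quantile normalization and cyclic loess lost the PI3K pathway list (adjusted p = 0.0618 and 0.0687) and gained ribosome biogenesis (0.0107 and 0.0266), leaving out dim probe sets lost the PI3K pathway list (0.079) and gained fatty acid synthesis (0.0378), and fry lost 10 lists and gained 2, while median centring passed the same 15. Tied probe sets are weighed among the other observations. No other cause of these shifts was tested, lost degrees of freedom included.

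Values near 0 turned sign. MYC was at -0.042 after quantile normalization, -0.0026 after median centring, -0.025 with array weights, -0.0054 after cyclic loess and between -0.074 and 0.063 without 1 array. IRS2 was at -0.0036 after quantile normalization, -0.0014 after median centring, -0.015 with the replicate block and between -0.14 and 0.14 without 1 array. The plasma cell list was at 0.021 without dim probe sets and between -0.044 and -0.0078 without 1 array, the Hodgkin list at 0.0030 with the replicate block and between -0.068 and 0.0030 without 1 array, and the ER chaperone list between -0.096 and 0.037 without 1 array. Without 1 array FOXO1 ranged from 0.04 to 0.13, CCND2 from -0.26 to -0.02, heat shock genes from 0.04 to 0.15 and oxidative phosphorylation from -0.05 to -0.02, with their signs kept. Quantile normalization put ER chaperones at -0.07, oxidative phosphorylation at -0.08, the Hodgkin list at -0.06, the plasma cell list at -0.05, MHC class I at -0.10, NRF2 targets at 0.00 and FOXO1 at 0.04. None of these passed a test in any of these settings, and the cause was not tested. The ACTB 3' minus 5' difference of single arrays deviated from the mean of the others by up to -0.193. The alternative offset was not run, because the table is not linear. Without dim probe sets some means were larger: B cell identity -0.43, ERK feedback genes 0.54, the BCL2 family 0.17, NRF2 targets 0.09 and stromal, endothelial and epithelial markers -0.20. Dim probe sets limit what can be seen: signal over background was not used here.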

Other observations

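Families of genes were grouped by their symbols after the data had been seen, and 17 families were tested with camera at the preset correlation. Histone genes had a mean log2 fold change of 0.36 and a median of 0.06 over 46 genes (adjusted p = 3.04e-06; adjusted p = 0.649 with an estimated correlation), and 7 of them rose, each by at least 1. The other 39 did not pass. The 7 had a median level of 6.68 on the DMSO arrays and the 39 one of 5.26. H2BC6, a core histone gene outside the fixed lists, rose by 1.35 ± 0.05. Dual specificity phosphatases, many of which act on MAP kinases, had a mean of 0.27 over 14 genes. DUSP4, DUSP5 and DUSP6 are also on the ERK feedback list, so the family is not separate from that list. Translation initiation factors had a mean of 0.12 over 37 genes. The adjusted p from camera was 0.0248 for the phosphatases and for the initiation factors, and 0.649 for each with an estimated correlation. Glutathione transferases had a mean of -0.09 over 14 genes, 13 of them below 0 (adjusted p = 0.0252; adjusted p = 0.649 with an estimated correlation), and GSTM1 fell by 0.35 ± 0.04 (limma adjusted p = 0.0551 with an intensity trend and robust prior) on a probe set that can bind its relatives. The sign of each of these 4 means was the same as deposited and after quantile normalization, median centring and cyclic loess, with 11, 9 and 11 histone genes rising after these and a mean of 0.07 for initiation factors after quantile normalization.

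All tests in what follows were chosen after the results were seen, though the list of BET inhibitor-induced genes was fixed before the data were examined. The rise of histone genes, HEXIM1 and DHRS2 was set against 3 explanations, and no other was tested. Signal shared between near-identical histone copies cannot be told apart from a rise of each H2A and H2B gene, because all 5 that rose are read by probe sets marked as shared, and of 2 genes above the array median on other probe sets 1 was higher by over 0.5 (H2BC12, at 1.32 ± 0.18; H2BC15 was at 0.01 ± 0.03). A larger share of cells in S phase would raise replication genes too, and their mean was -0.282 ± 0.0882 (SE over arrays). A response like that to BET inhibitors cannot be told apart from an effect through PI3K: outside histone genes and HEXIM1 the fixed list has 1 measured member, so that 0 of 1 being higher decides nothing (SERPINI1 reads 4.74 on every array, a dim and tied probe set), and no second inhibitor is in the design.

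Replication genes were lower while mitotic genes were higher. A shift with intensity alone is argued against, since random lists matched on expression differed by a mean of 0.0037, against 0.554 ± 0.0256 observed (SE over arrays). The random lists differed by at most 0.314. That is no bound on the spread of the real lists, whose members had estimated correlations of 0.395 (mitosis) and 0.329 (replication). A change in the share of dividing cells alone would move both lists in 1 direction, and the difference of 0.554 goes against it. A larger share of cells in G2 or mitosis was not tested and stays open, as DNA content was not used here.

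The number of genes past the threshold differed between settings, while the signs of the 70 genes, which were chosen on these same arrays, did not. Of the 8746 probe sets, 2836 (32.4%) held identical values on at least 2 of the 3 DMSO arrays and 785 (8.98%) on both LY294002 arrays, 3325 in all. Such ties are a candidate cause of the low count: without them limma's prior degrees of freedom rose from 1.5 to 4.27 and the count from 70 to 510. In 100 random removals of as many probe sets of like intensity the values were 1.49 to 1.72 and 33 to 115 genes. These removals were matched on intensity and not on spread. Tied probe sets have a low spread within a group, so the comparison cannot tell ties from low spread as such. Without tied probe sets CDKN1B (1.21 ± 0.24, limma adjusted p = 0.0214), FOXO3 (0.77 ± 0.15, 0.0198), BCL6 (0.37 ± 0.08, 0.0233) and TNFRSF8 (-0.68 ± 0.14, 0.0263) passed as well. Their passing rests on a removal that used the groups, so they are not counted as changed here. The 10 splits of the 5 arrays into 3 and 2 are too few for a share under 0.05; 1 of them, the real one, gave 70 genes, and the highest of the others 0.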
